A study of Mus musculus with 8 samples.

How the data were processed

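RNA from pools of 70 hand-picked tdTomato-positive cells was amplified with Smart-seq2 and sequenced, per the labels' protocols. The deposited table holds FPKM (fragments scaled by transcript length and by the mapped fragments of the library) per gene and library, made by the authors. HISAT2, SAMtools 0.1.18, Cufflinks, HTSeq and the build mm10 are named in the submitters' processing notes, with no role or order given, and the annotation release was not given in the sources used here. FPKM divides by gene length and library total, so abundant genes in a library lower its other values. Smart-seq2 does not mark strand, so reads of a gene and of an antisense partner cannot be told apart. Reads shared by near-identical copies, such as ribosomal protein genes, their pseudogenes and the globins, make those values uncertain. All 37 mitochondrially encoded genes were listed at 0 in every library, and 0 of the values of 16 genes used by every cell were. The number of genes above 0 equalled the number of detected genes in the labels in 8 of 8 libraries.

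Of 48555 lines, 65 repeated a gene ID (49 IDs, all with identical values), which left 48490 genes. No libraries held identical values. FPKM summed to 293194 to 382101 per library. Read counts are unknown, so no counting intervals were computed. Relative depth was read from the most frequent ratio between libraries among genes with a mean FPKM below 2, and spanned 1.29-fold. Values were used as deposited, as log2(FPKM + 1), without further scaling, and fold changes on this scale understate the change of low genes. Genes with an FPKM of at least 1 in at least 2 of 8 libraries were tested, 12888 in all.

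Groups came from the labels. All 3 groups were fitted together with limma 3.58.1 in R 4.3.3 (group means, moderated with a mean-variance trend), so that GoF and WT, with 2 libraries each, shared the estimate of the spread. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Total degrees of freedom were 10.1, of which 5.1 came from the prior. Libraries of the groups compared did not overlap in 48.0% of genes for GoF against WT (33.3% by chance), 21.4% for LoF against WT (13.3% by chance) and 33.5% for GoF against LoF (13.3% by chance). The tests, the 31 gene lists, the naming rule and a set of other settings were fixed before the data were examined. The 27 lists with at least 4 tested members were tested with camera, two-sided, with a preset inter-gene correlation of 0.01, adjusted over 81 tests. Lists moved numbered 13 in GoF against WT, 10 in LoF against WT and 16 in GoF against LoF. With an estimated correlation 0 lists passed (smallest adjusted p = 0.13). In that setting camera also took its degrees of freedom from the libraries rather than the genes, so more than the correlation changed. In GoF against WT, the pericyte and myeloid lists had estimated correlations of -0.072 and -0.012, below the preset value. Their adjusted p in camera still went from 0.00222 and 0.000578 to 0.13. The lost calls therefore cannot be assigned to correlation between genes alone. The test fry, which asks whether the genes of a list move one way and compares them with no other genes, called 9, 8 and 14 lists. The Irx, megakaryocyte, skeletal muscle and mitochondrial lists had 2, 3, 2 and 0 tested members and were not tested. Ahsp and Acta1 matched no gene. Counts of list members below are of tested genes. The adipocyte, osteocyte and Wnt target lists held 33, 12 and 23 genes, of which 21, 9 and 16 were tested. The rest of these did not reach the filter on FPKM.

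Named genes followed a fixed rule. It took, per comparison, the 8 largest fold changes in each direction among called genes without overlap between libraries, leaving out predicted or unnamed genes, up to 4 leading members of each list that passed, up to 4 called members of any list, a fixed set of pathway and lineage genes whether changed or not, and the 6 largest ordered genes in each direction. A gene whose group is at 0 in all libraries is given as listed at 0, without a fold. The other settings fixed then were a pseudocount of 0.1, no filter on low values, median ratio scaling, quantile normalization, only the groups compared, no mean-variance trend, the replicate number as a block, an estimated correlation for lists, and leaving out each library. Sex as a covariate (Y-linked transcripts or Xist), a fit without LoF libraries 2 and 3, and fry were added after the data were seen.

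The code was tested on simulated data drawn from the means and spreads of the 12888 genes, in 10 sets per comparison with 200 genes changed. For GoF against WT, 0.8%, 24.4%, 74.2% and 92.6% of genes changed by 1, 2, 3 and 4 on the log2 scale were found. For LoF against WT these shares were 2.6%, 41.8%, 87.4% and 97.8%, and for GoF against LoF 3.4%, 40.2%, 83.2% and 96.6%. False calls were 5.7%, 6.4% and 7.0% of calls in the same order. A list shifted by 1 was found in 10 of 10 sets in each comparison. Genes were drawn independently, with a spread per gene shared by all groups. The real osteoblast list, the one shifted, had an estimated correlation of 0.175, and the endothelial list one of 0.742. These shares therefore check the code and are not error rates for the real data. Coordinates of genes are those of the deposited table with the first base counted as 1, and exons and transcript lengths came from GENCODE M21. Tables and figures were made with Python 3.11.15 and matplotlib 3.10.9.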

Results

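Cells descended from hypertrophic chondrocytes, the enlarged cells at the lower end of the growth plate, were profiled in mice with lost or stabilised β-catenin, the effector of canonical Wnt signalling. Cre recombinase driven by Col10a1, a gene of hypertrophic chondrocytes, switched on the red fluorescent protein tdTomato and recombined Ctnnb1, the gene of β-catenin. LoF (loss of function) mice carried the deletion on both alleles. GoF (gain of function) mice lacked exon 3 on 1 allele, the part that marks the protein for degradation. WT mice carried the Cre and the reporter alone. The study title poses the question as a choice between adipogenic and osteogenic differentiation. Each library came from 70 tdTomato-positive cells of the proximal tibia at postnatal day 5, with 4 LoF, 2 GoF and 2 WT libraries. The labels do not state whether the libraries of a group come from separate animals, so p-values measure the spread between these libraries, which may be technical. Between 12604 and 13962 genes were above 0 per library. Read totals are unknown, and the step between low values put relative depth between 0.895 and 1.153 of WT library 2. Spearman's rho across genes, which are not independent replicates, was 0.766 to 0.826 among the LoF libraries, 0.860 between the GoF libraries and 0.839 between the WT libraries, against 0.635 to 0.731 between GoF and LoF, 0.736 to 0.785 between GoF and WT, and 0.736 to 0.811 between LoF and WT, which overlaps the range among the LoF libraries. FPKM values are given below as mean ± SD over n = 4 LoF, n = 2 GoF and n = 2 WT libraries. Folds are ratios of these means, while log2 fold changes are differences of mean log2(FPKM + 1).

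The targeted gene, Ctnnb1 (ENSMUSG00000006932.16, chromosome 9, 120929216 to 120960507, mm10), had an FPKM of 74.96 ± 7.17 (SD, n = 4) in LoF, 79.3 ± 10.3 (SD, n = 2) in GoF and 142 ± 5.98 (SD, n = 2) in WT. All 6 mutant libraries lay below both WT libraries, but neither difference passed the test (limma, log2 fold change -0.91, SE 0.24, adjusted p = 0.110 for LoF, and -0.83, SE 0.27, adjusted p = 0.176 for GoF). The table holds 1 value per gene, so it does not show which exons were transcribed. Axin2 (ENSMUSG00000000142.15, chromosome 11, 108920349 to 108950783), a feedback inhibitor and direct target of the pathway, was listed at 0 in all 4 LoF libraries and WT library 1, at 0.323 in WT library 2, and at 5.26 and 2.81 in the GoF libraries. It was higher in GoF than in WT (log2 fold change 2.08, SE 0.45, adjusted p = 0.0429), a call that ended in 11 of 15 alternatives (adjusted p up to 0.271), and than in LoF (adjusted p = 0.00484), where the call ended in 1 of 15 (adjusted p = 0.0515).

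**Figure D1:**
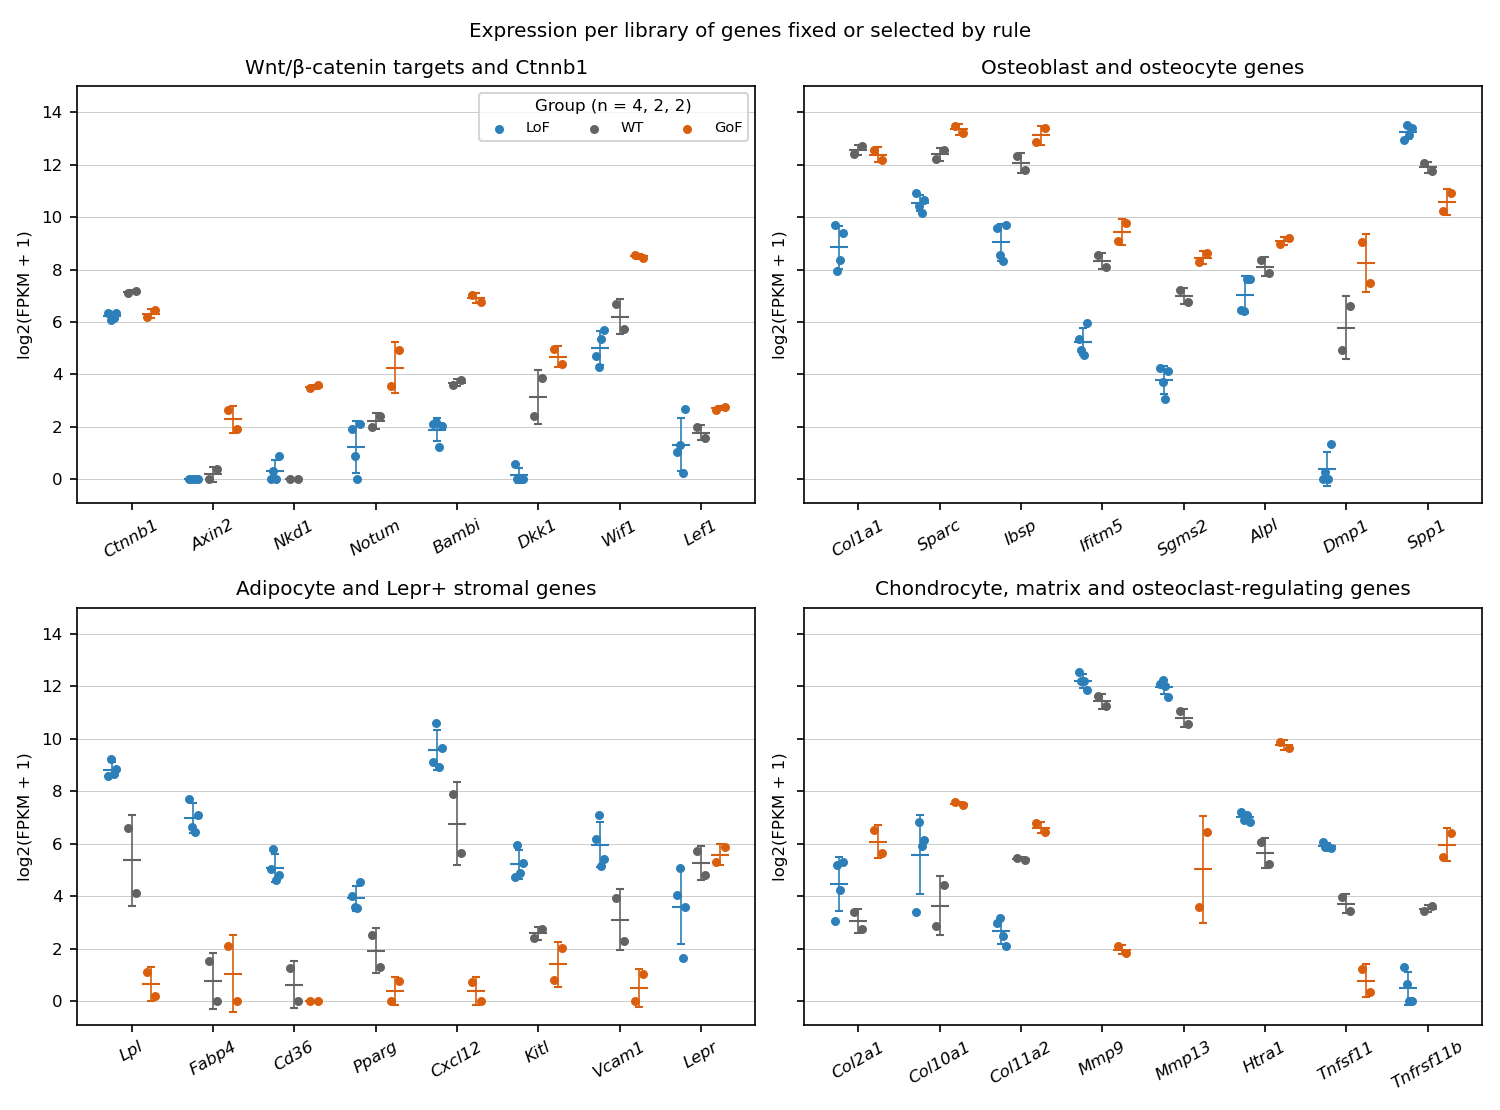
Expression of named genes as log2(FPKM + 1), where each dot is a library and bars give the group mean and SD (n = 4 LoF, 2 WT, 2 GoF). Col1a1 averaged 517 FPKM in LoF against 6076 in WT, and Mmp9 averaged 2.92 FPKM in GoF against 4777 in LoF.

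GoF against LoF asks what differs between the opposite alleles, the widest step in β-catenin activity in the design. In GoF, 18 of 26 osteoblast genes, 7 of 9 osteocyte genes, 9 of 16 Wnt targets and 6 of 20 cartilage genes were higher, and 3 osteoblast genes were lower. In LoF, 8 of 21 adipocyte genes and 12 of 19 marrow stromal genes were higher. These 6 lists passed in camera with the preset correlation and none passed with an estimated correlation (smallest adjusted p = 0.13). Mmp9 (ENSMUSG00000017737.2, chromosome 2, 164940780 to 164955850), a gelatinase, averaged 4777 ± 892 FPKM in LoF and 2.92 ± 0.508 in GoF (log2 fold change -10.24, SE 0.24, adjusted p = 1.35e-08). The collagenase Mmp13 averaged 4082 ± 704 and 48.8 ± 53.5 FPKM (log2 fold change -6.96, SE 0.60, adjusted p = 0.000148). Of 12888 genes tested, 769 were higher and 732 lower in GoF, with 983 and 658 under median ratio scaling and 639 and 798 with a pseudocount of 0.1. The median log2 fold change of all tested genes was -0.17 here, and -0.05 with median ratio scaling and -0.03 with quantile normalization.

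Of 26 osteoblast genes, 18 were higher in GoF than in LoF, 3 were lower and 5 did not pass, with the same counts of 18 and 3 adjusted over the list alone (camera, adjusted p = 3.47e-11, and adjusted p = 0.13 with an estimated correlation). Ibsp, the bone sialoprotein gene, averaged 9070 ± 2268 FPKM in GoF and 572 ± 263 in LoF (log2 fold change 4.08, SE 0.40, adjusted p = 0.000248). Col1a1 (ENSMUSG00000001506.10, chromosome 11, 94936224 to 94953042), which encodes a chain of type I collagen, averaged 5358 ± 1035 and 517 ± 277 FPKM (log2 fold change 3.53, SE 0.44, adjusted p = 0.000886). Sgms2, Ifitm5 and Sparc were 26.2-fold, 18.2-fold and 6.90-fold higher, and Alpl 3.87-fold. Bglap had a log2 fold change of 4.54 (SE 0.90, adjusted p = 0.00988). The osteoblast transcription factor Sp7 was 3.40-fold higher (adjusted p = 0.0112), while Runx2 averaged 26.7 ± 9.69 and 26.2 ± 6.04 FPKM and did not pass (adjusted p = 0.991). The 3 members that were lower were Spp1, Tnc and Mmp14. Spp1, the osteopontin gene, averaged 1570 ± 524 FPKM in GoF and 9836 ± 1823 in LoF (log2 fold change -2.67, SE 0.26, adjusted p = 0.000241). Of 9 osteocyte genes, 7 were higher, 0 lower and 2 not past, and 7 were higher adjusted over the list alone (camera, adjusted p = 2.85e-08, and adjusted p = 0.13 with an estimated correlation). Dmp1 (ENSMUSG00000029307.7, chromosome 5, 104202613 to 104214102), a matrix phosphoprotein gene of osteocytes, averaged 350 ± 245 FPKM in GoF and 0.435 ± 0.744 in LoF (log2 fold change 7.85, SE 0.62, adjusted p = 9.42e-05). Pdpn had a log2 fold change of 5.88 (SE 0.84, adjusted p = 0.0019).

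Of 16 Wnt/β-catenin target genes, 9 were higher in GoF, 0 lower and 7 not past, and 12 were higher adjusted over the list alone (camera, adjusted p = 1.36e-10, and adjusted p = 0.13 with an estimated correlation). Bambi was 42.4-fold higher (log2 fold change 5.02, SE 0.38, adjusted p = 7.59e-05). The secreted Wnt inhibitor genes Dkk1, also on the osteocyte list, and Wif1 had log2 fold changes of 4.53 (SE 0.53) and 3.50 (SE 0.42), and Notum one of 3.02 (SE 0.67, adjusted p = 0.0176). Lef1 averaged 5.56 ± 0.334 FPKM in GoF and 2.05 ± 2.35 in LoF (adjusted p = 0.209), and Tcf7 10.1 ± 5.59 and 2.74 ± 0.785 (adjusted p = 0.069), and neither passed. Of 20 cartilage genes, 6 were higher, 0 lower and 14 not past, and 7 were higher adjusted over the list alone (camera, adjusted p = 2.69e-05, and adjusted p = 0.17 with an estimated correlation). Col11a2 and Col11a1 were 17.3-fold and 7.64-fold higher, and Chad and Comp had log2 fold changes of 4.21 (SE 0.61) and 3.22 (SE 0.62). Col2a1, Acan and Sox9 did not pass (adjusted p = 0.119, 0.794 and 0.5). Of 13 hypertrophic chondrocyte genes, 5 were higher and 2 lower, also adjusted over the list alone (camera, adjusted p = 0.0422, and adjusted p = 0.25 with an estimated correlation). Panx3 was 12.1-fold and Mef2c 4.53-fold higher. Phospho1 and Scin were also higher, at 8.00 ± 2.25 and 6.44 ± 5.19 FPKM in GoF and at or below 1.00 in each LoF library. Ihh was listed at 0 in all LoF libraries and at 1.46 and 3.91 FPKM in GoF (adjusted p = 0.016). The members that were lower were Mmp13 and Cd200, and Col10a1 did not pass (adjusted p = 0.163). The call of the hypertrophic list ended in 5 of 17 alternatives, which were quantile normalization, leaving out LoF replicate 4, GoF replicate 1 or GoF replicate 2, and sex as a covariate, with an adjusted p of up to 0.392.

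Of 21 adipocyte genes, 8 were lower in GoF than in LoF, 1 was higher (Scd1) and 12 did not pass, and 12 were lower and 1 higher adjusted over the list alone (camera, adjusted p = 2.69e-05, and adjusted p = 0.13 with an estimated correlation). Lpl (ENSMUSG00000015568.16, chromosome 8, 68880491 to 68907448), the lipoprotein lipase gene, averaged 460 ± 95.8 FPKM in LoF and 0.648 ± 0.732 in GoF (log2 fold change -8.18, SE 0.57, adjusted p = 5.81e-05). Fabp4 (ENSMUSG00000062515.3, chromosome 3, 10204088 to 10208576), a fatty acid carrier of adipocytes, averaged 132 ± 56.2 and 1.64 ± 2.31 FPKM (log2 fold change -5.92, SE 0.64, adjusted p = 0.000397). Pparg, the main transcription factor of adipocyte differentiation, was lower (log2 fold change -3.54, SE 0.52, adjusted p = 0.0023). Cd36 and Cebpa were listed at 0 in both GoF libraries and averaged 34.3 ± 14.2 and 4.80 ± 1.56 FPKM in LoF (adjusted p = 0.000266 and 0.00661). Adipoq, the adiponectin gene, was listed at 0 in GoF, ranged from 0.567 to 62.1 FPKM in LoF and did not pass (adjusted p = 0.0921), and neither did Apoe (adjusted p = 0.885). Of 19 genes of Lepr-positive marrow stromal cells, 12 were lower, 0 higher and 7 not past, and 13 were lower and 2 higher adjusted over the list alone (camera, adjusted p = 7.86e-07, and adjusted p = 0.22 with an estimated correlation). Cxcl12 (ENSMUSG00000061353.11, chromosome 6, 117168535 to 117181367), a chemokine that retains blood stem cells in the marrow, averaged 853 ± 499 FPKM in LoF and 0.337 ± 0.476 in GoF (log2 fold change -9.21, SE 0.62, adjusted p = 5.81e-05). Pdgfrb, Vcam1 and Kitl had log2 fold changes of -5.17 (SE 0.46), -5.45 (SE 0.63) and -3.81 (SE 0.48). Lepr itself averaged 47.5 ± 13.3 FPKM in GoF and 15.4 ± 12.8 in LoF and did not pass (adjusted p = 0.133).

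Tnfsf11 (ENSMUSG00000022015.8, chromosome 14, 78277445 to 78308043), which encodes the osteoclast-inducing ligand RANKL, averaged 59.6 ± 4.06 FPKM in LoF and 0.785 ± 0.746 in GoF (log2 fold change -5.15, SE 0.36, adjusted p = 5.81e-05). Tnfrsf11b (ENSMUSG00000063727.3, chromosome 15, 54250619 to 54278484), which encodes its decoy receptor osteoprotegerin, averaged 0.516 ± 0.699 FPKM in LoF and 63.9 ± 27.3 in GoF (log2 fold change 5.46, SE 0.51, adjusted p = 0.000202). Of 15 matrix-degrading enzymes and their inhibitors, 7 were lower in GoF, 2 higher and 6 not past, and 9 were lower and 3 higher adjusted over the list alone (camera, adjusted p = 0.0138, and adjusted p = 0.26 with an estimated correlation). The lower members included Mmp14, 2.80-fold, and Timp3, an inhibitor of these enzymes, with a log2 fold change of -3.99 (SE 0.53). The higher ones were the serine protease gene Htra1, 6.77-fold, and Mmp16, 9.20-fold. Without LoF replicate 1, the 1 of 17 alternatives that ended the list's call, its adjusted p was 0.058.

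Smaller groups also moved between GoF and LoF. Of 10 Notch pathway genes, Hey1, Heyl and Notch1 were lower and 7 did not pass, and 5 were lower adjusted over the list alone (camera, adjusted p = 0.00261, and adjusted p = 0.26 with an estimated correlation). Of 9 Hedgehog pathway genes, 4 were lower, among them Ptch1, Gli2 and Smo, and 5 did not pass, and 5 were lower and 1 higher adjusted over the list alone (camera, adjusted p = 0.00391, and adjusted p = 0.26 with an estimated correlation). Of 18 cell cycle genes, Aurkb, Top2a, Pcna and Mcm6 were lower and 14 did not pass, and 5 were lower adjusted over the list alone (camera, adjusted p = 0.000562, and adjusted p = 0.41 with an estimated correlation). The calls of Pcna and Mcm6 each ended in 12 of 17 alternatives (adjusted p up to 0.381 and 0.344). Of 7 pericyte and smooth muscle markers, Myl9, Acta2 and Mcam were lower and 4 did not pass, and 4 were lower adjusted over the list alone (camera, adjusted p = 0.000708, and adjusted p = 0.13 with an estimated correlation). Of 13 genes of the unfolded protein and integrated stress response, 6 were higher and 7 not past, also with 6 adjusted over the list alone (camera, adjusted p = 0.000221, and adjusted p = 0.22 with an estimated correlation). Xbp1, a transcription factor gene of that response, was 11.7-fold higher, and Herpud1 7.36-fold. Of 14 hypoxia and glycolysis genes, Ndrg1 and Aldoa were higher and 12 did not pass, and 3 were higher adjusted over the list alone (camera, adjusted p = 0.00409, and adjusted p = 0.32 with an estimated correlation). Of 13 immediate early genes, Atf3 was higher and 12 did not pass, and 2 were higher adjusted over the list alone (camera, adjusted p = 0.0472, and adjusted p = 0.57 with an estimated correlation). That call ended in 6 of 17 alternatives, with an adjusted p of up to 0.224. Of 81 ribosomal protein genes, 7 were lower, 2 higher (Rps3a3 and Rps3a2) and 72 not past, and 12 were lower and 2 higher adjusted over the list alone (camera, adjusted p = 0.000578, and adjusted p = 0.57 with an estimated correlation). The ribosomal call ended without GoF replicate 1 and without LoF libraries 2 and 3, with an adjusted p of up to 0.0993. Genes resembling ribosomal RNA took 11.98% and 12.1% of the FPKM in GoF and 3.64% to 5.80% in LoF.

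Among other genes with large differences, Gal, the galanin gene, averaged 391 ± 146 FPKM in GoF and 1.83 ± 3.66 in LoF (log2 fold change 7.80, SE 0.83, adjusted p = 0.000352). Car12, Slc16a4 and Rps3a3 had log2 fold changes of 5.79 (SE 0.51), 5.85 (SE 0.67) and 5.64 (SE 1.24). Rps3a3 was at 1.13 and 106.5 FPKM in the WT libraries, and reads shared by near-identical copies make such values uncertain. Lipi and Egfem1 were listed at 0 in all 4 LoF libraries and averaged 67.3 ± 30.3 and 56.6 ± 5.43 FPKM in GoF. Wisp2, Mest and Sstr2 had log2 fold changes of -6.59 (SE 0.42), -5.73 (SE 0.47) and -5.58 (SE 0.42). Irx5, an Iroquois transcription factor gene, was higher in GoF (log2 fold change 2.77, SE 0.58, adjusted p = 0.0127), and Irx3 averaged 3.97 ± 1.96 FPKM in GoF and 1.30 ± 0.646 in LoF and did not pass (adjusted p = 0.187). Of the 100 named genes called in this comparison, 48 kept their call under all 17 alternatives. Among these were Mmp9, Cxcl12, Lpl, Fabp4, Pparg, Dmp1, Col1a1, Ibsp, Tnfsf11 and Tnfrsf11b. Another 7 lost their call in over 0.5 of the alternatives (Mcm6, Smo, Pcna, Rpl36a, Aldoa, Fdps and Dnajb9). Both GoF libraries and LoF libraries 2 and 3 held Y-linked transcripts, while LoF libraries 1 and 4 held Xist. Leaving out LoF libraries 2 and 3 thus set Y-linked GoF libraries against Xist LoF libraries alone. That fit does not remove a difference by sex, and it also had fewer libraries. The count of 1501 changed genes was 414 without GoF replicate 1, 525 without GoF replicate 2, 974 with sex as a covariate and 848 without LoF libraries 2 and 3.

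**Figure D2:**
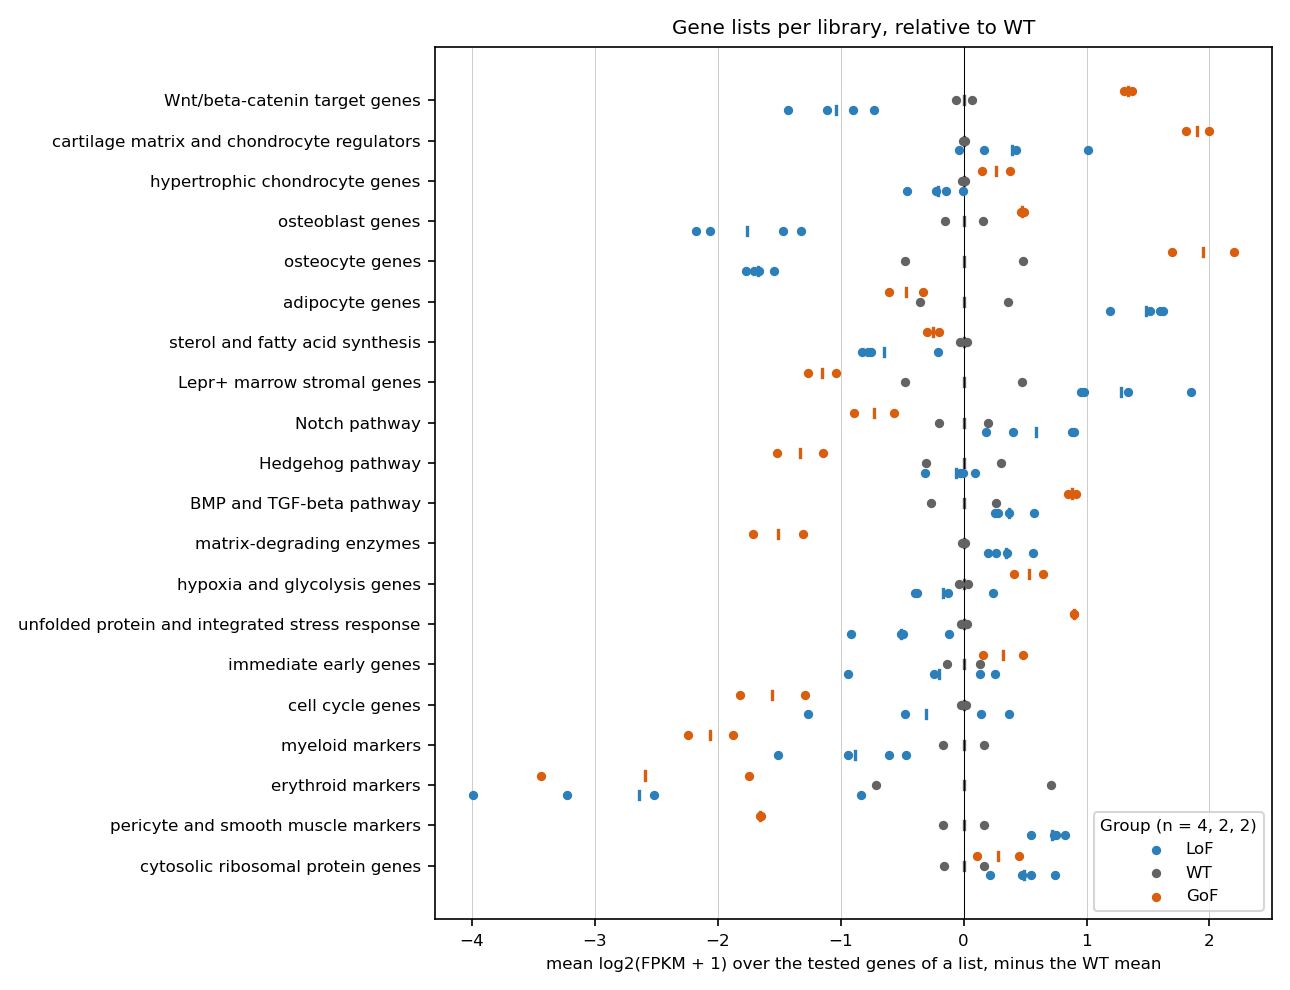
Mean log2(FPKM + 1) over the tested genes of each list that passed in any comparison, minus the WT mean, with 1 dot per library (n = 4 LoF, 2 WT, 2 GoF) and short vertical bars for group means. Osteoblast genes averaged -1.76 in LoF and 0.48 in GoF, adipocyte genes 1.48 and -0.47, and the ribosomal protein genes, 0.28 in GoF, turned direction in GoF against WT under quantile normalization.

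LoF against WT asks what loss of β-catenin changes. Of the osteoblast genes 10 of 26 fell, of the osteocyte genes 3 of 9 fell, and of the adipocyte genes 3 of 21 rose (Fabp4, Cd36 and Lpl). These 3 lists passed in camera with the preset correlation and not with an estimated correlation (adjusted p = 0.13, 0.17 and 0.13). Col1a1 fell from 6076 ± 856 FPKM in WT to 517 ± 277 in LoF (log2 fold change -3.72, SE 0.44, adjusted p = 0.00657), and Dmp1 from 63.6 ± 48.4 to 0.435 ± 0.744 (log2 fold change -5.37, SE 0.62, adjusted p = 0.00657). Fabp4 rose from 0.941 ± 1.33 to 132 ± 56.2 FPKM (log2 fold change 6.20, SE 0.64, adjusted p = 0.00586). Of 12888 genes, 73 rose and 86 fell, and 80 rose and 147 fell with quantile normalization.

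Of 26 osteoblast genes, 10 fell in LoF, 1 rose and 15 did not pass, and 17 fell and 1 rose adjusted over the list alone (camera, adjusted p = 5.32e-16, and adjusted p = 0.13 with an estimated correlation). Sgms2, Ifitm5, Ibsp and Sparc were 9.43-fold, 8.27-fold, 7.65-fold and 3.59-fold lower, and Smpd3 12.3-fold. The member that rose was Spp1, from 3843 ± 556 to 9836 ± 1823 FPKM (log2 fold change 1.34, SE 0.26, adjusted p = 0.0416). Runx2, Sp7, Alpl and Bglap did not pass (adjusted p = 0.296, 0.11, 0.269 and 0.181). Of 9 osteocyte genes, Dmp1, Tnfrsf11b and Dkk1 fell and 6 did not pass, and 4 fell adjusted over the list alone (camera, adjusted p = 3.01e-05, and adjusted p = 0.17 with an estimated correlation). Of 16 Wnt target genes, Dkk1 fell and 15 did not pass, and 6 fell adjusted over the list alone (camera, adjusted p = 3.01e-05, and adjusted p = 0.13 with an estimated correlation). Bambi averaged 2.82 ± 0.978 FPKM in LoF and 11.9 ± 1.13 in WT (adjusted p = 0.0581), and Tcf7 2.74 ± 0.785 and 13.1 ± 5.14 (adjusted p = 0.0971).

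Of 21 adipocyte genes, Fabp4, Cd36 and Lpl rose in LoF and 18 did not pass, and 7 rose adjusted over the list alone (camera, adjusted p = 7.86e-07, and adjusted p = 0.13 with an estimated correlation). The fatty acid transporter gene Cd36 rose from 0.691 ± 0.977 to 34.3 ± 14.2 FPKM (log2 fold change 4.44, SE 0.51, adjusted p = 0.00657), and Lpl from 55.9 ± 55.8 to 460 ± 95.8 (log2 fold change 3.47, SE 0.57, adjusted p = 0.0243). Pparg averaged 14.7 ± 5.49 FPKM in LoF and 3.10 ± 2.30 in WT and did not pass (adjusted p = 0.112). Plin2, Cebpa and Adipoq did not pass either (adjusted p = 0.0546, 0.219 and 0.552). Of 19 Lepr-positive stromal genes, Kitl rose and 18 did not pass, and 9 rose adjusted over the list alone (camera, adjusted p = 5.77e-06, and adjusted p = 0.25 with an estimated correlation). Cxcl12 averaged 853 ± 499 FPKM in LoF and 143 ± 132 in WT (adjusted p = 0.0671). Lepr itself averaged 15.4 ± 12.8 and 39.2 ± 17.2 FPKM (adjusted p = 0.382). Tnfsf11 rose 4.85-fold (log2 fold change 2.21, SE 0.36, adjusted p = 0.0232), and Tnfrsf11b fell (log2 fold change -3.03, SE 0.51, adjusted p = 0.0259). The calcium-binding protein gene S100a6 rose from 21.5 ± 12.8 to 449 ± 138 FPKM (adjusted p = 0.00586). Igf2, Igfbp2, Pcbd2 and Ptx3 had log2 fold changes of 4.26 (SE 0.52), 4.00 (SE 0.55), 4.13 (SE 0.60) and 3.50 (SE 0.68). LoF library 2 held transcripts of B cells (Ms4a1 at 5.29 and Cd74 at 21.1 FPKM), and LoF library 3 of endothelial cells (Emcn at 38.5, Egfl7 at 34.5 and Esam at 10.6 FPKM), genes chosen after their values were seen.

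Of 17 sterol and fatty acid synthesis genes, which moved down as a list, 0 passed the test of single genes and 3 fell adjusted over the list alone (camera, adjusted p = 0.000708, and adjusted p = 0.25 with an estimated correlation). Of 13 stress response genes, also down as a list, 0 passed and 2 fell adjusted over the list alone (camera, adjusted p = 0.0184, and adjusted p = 0.37 with an estimated correlation). Without WT replicate 2 the adjusted p of that list was 0.0615, the largest of 17 alternatives. Of 81 ribosomal protein genes, Rpl21, Rpl26 and Rps24 rose and 78 did not pass, and 39 rose adjusted over the list alone (camera, adjusted p = 5.32e-16, and adjusted p = 0.26 with an estimated correlation). Genes resembling ribosomal RNA took 3.64% to 5.80% of the FPKM in LoF and 13.5% and 14.0% in WT. Of 13 myeloid markers, Mpo fell and 12 did not pass, and 2 fell adjusted over the list alone (camera, adjusted p = 0.0156, and adjusted p = 0.17 with an estimated correlation). That call ended with no filter, with the replicate block and without WT replicate 1, with an adjusted p of up to 0.154. Of 7 erythroid markers, down as a list, 0 passed and 2 fell adjusted over the list alone (camera, adjusted p = 0.000749, and adjusted p = 0.17 with an estimated correlation). The globin gene Hbb-bs was listed at 1007 and 3760 FPKM in WT and from 25.6 to 1040 in LoF. Kel, a red cell antigen gene, and Stfa1 were listed at 0 in all LoF libraries and averaged 10.4 ± 1.19 and 17.9 ± 20.3 FPKM in WT (adjusted p = 0.00586 and 0.0374). Slc36a2, Tiam1 and Chn1os1 had log2 fold changes of -3.30 (SE 0.59), -3.30 (SE 0.46) and -3.27 (SE 0.63). LoF libraries 2 and 3 held Y-linked transcripts and no Xist, while LoF libraries 1 and 4 and both WT libraries held Xist. Sex was thus not balanced between LoF and WT, and leaving out LoF libraries 2 and 3 compared Xist libraries alone. That fit also had fewer libraries, so its lost calls cannot be assigned to sex or to number. In limma, 0 genes passed with only LoF and WT in the fit (1569 at an unadjusted p under 0.05) or without LoF libraries 2 and 3 (1479), 1 with the replicate block, 14 with sex as a covariate, 53 with no filter, 54 with no mean-variance trend and 83 with a pseudocount of 0.1. The count of 159 was 3 without WT replicate 2, 36 without WT replicate 1 and 42 without LoF replicate 2, and 0 of the 39 named genes called kept their call under all 17 alternatives, while 20 lost it in over 0.5 of them, among them Tnfrsf11b, Dkk1, Tnfsf11, Lpl, Spp1 and Kitl.

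GoF against WT asks what stabilised β-catenin changes. Of the Wnt targets 4 of 16 rose, of the cartilage genes 3 of 20 and of the osteocyte genes 2 of 9, while 3 of 19 marrow stromal genes, 4 of 15 matrix-degrading enzymes and inhibitors, 2 of 9 Hedgehog genes and 1 of 18 cell cycle genes fell. These 7 lists passed in camera with the preset correlation and none passed with an estimated correlation (smallest adjusted p = 0.13). Mmp9 fell from 2785 ± 540 FPKM in WT to 2.92 ± 0.508 in GoF (log2 fold change -9.47, SE 0.28, adjusted p = 1.26e-07), and Cxcl12 from 143 ± 132 to 0.337 ± 0.476 (log2 fold change -6.40, SE 0.72, adjusted p = 0.00268). Htra1 rose from 51.0 ± 20.1 to 870 ± 107 FPKM (log2 fold change 4.12, SE 0.32, adjusted p = 0.000514). Of 12888 genes, 182 rose and 116 fell, with 112 and 127 under a pseudocount of 0.1 and 210 and 92 with no filter.

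Of 16 Wnt target genes, Bambi, Nkd1, Wif1 and Axin2 rose in GoF and 12 did not pass, and 6 rose adjusted over the list alone (camera, adjusted p = 2.6e-06, and adjusted p = 0.13 with an estimated correlation). Bambi rose from 11.9 ± 1.13 to 120 ± 15.4 FPKM (log2 fold change 3.23, SE 0.44, adjusted p = 0.00537), and Wif1 rose 4.72-fold. Nkd1, a feedback inhibitor gene, was listed at 0 in both WT libraries and averaged 10.5 ± 0.586 FPKM in GoF (adjusted p = 0.00691). Of 20 cartilage genes, Comp, Chad and Snorc (3110079O15Rik) rose and 17 did not pass, and 12 rose and 1 fell adjusted over the list alone (camera, adjusted p = 1.01e-07, and adjusted p = 0.13 with an estimated correlation). Comp, a cartilage matrix glycoprotein gene, rose (log2 fold change 4.97, SE 0.72, adjusted p = 0.00699). Col2a1 averaged 69.5 ± 29.4 FPKM in GoF and 7.56 ± 2.72 in WT (adjusted p = 0.0545), and Col10a1 averaged 184 ± 8.604 and 13.4 ± 10.1 (adjusted p = 0.0654), and neither passed. Of 9 osteocyte genes, Pdpn and Ackr3 rose and 7 did not pass, and 6 rose adjusted over the list alone (camera, adjusted p = 2.69e-05, and adjusted p = 0.17 with an estimated correlation). Pdpn rose (log2 fold change 5.57, SE 0.96, adjusted p = 0.0165), and Dmp1, at 350 ± 245 FPKM in GoF and 63.6 ± 48.4 in WT, did not pass (adjusted p = 0.122). The osteoblast list did not pass (camera, adjusted p = 0.0751), with Msx2 higher, Tnc and Mmp14 lower, and 23 of 26 members not past. Col1a1 averaged 5358 ± 1035 FPKM in GoF and 6076 ± 856 in WT (adjusted p = 0.927). Of 19 BMP and TGF-β pathway genes, Id1 and Bmp2 rose, Ctgf fell and 16 did not pass, and 4 rose and 1 fell adjusted over the list alone (camera, adjusted p = 0.00145, and adjusted p = 0.26 with an estimated correlation).

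Of 15 matrix-degrading enzymes and their inhibitors, Mmp9, Mmp13, Timp3 and Mmp14 fell in GoF, Htra1 rose and 10 did not pass, and 6 fell and 1 rose adjusted over the list alone (camera, adjusted p = 0.00261, and adjusted p = 0.21 with an estimated correlation). With only GoF and WT in the fit, the 1 of 17 alternatives that ended that call, its adjusted p was 0.0809. Mmp13 fell (log2 fold change -5.79, SE 0.70, adjusted p = 0.0033). Of 19 Lepr-positive stromal genes, Cxcl12, Pdgfrb and Csf1 fell and 16 did not pass, and 4 fell and 2 rose adjusted over the list alone (camera, adjusted p = 0.000708, and adjusted p = 0.34 with an estimated correlation). Lpl fell (log2 fold change -4.71, SE 0.66, adjusted p = 0.00645), while the adipocyte list did not pass (camera, adjusted p = 0.222), and neither did Pparg (adjusted p = 0.268). Tnfsf11 fell (log2 fold change -2.94, SE 0.41, adjusted p = 0.00643), and Tnfrsf11b averaged 63.9 ± 27.3 FPKM in GoF and 10.5 ± 1.10 in WT (adjusted p = 0.0682). Of 9 Hedgehog pathway genes, Ptch1 and Gli2 fell and 7 did not pass, and 4 fell adjusted over the list alone (camera, adjusted p = 0.000562, and adjusted p = 0.23 with an estimated correlation). Of 18 cell cycle genes, Aurkb fell and 17 did not pass, and 6 fell adjusted over the list alone (camera, adjusted p = 4.66e-07, and adjusted p = 0.26 with an estimated correlation). Of 7 pericyte and smooth muscle markers, Myl9 and Acta2 fell and 5 did not pass, and 3 fell adjusted over the list alone (camera, adjusted p = 0.00222, and adjusted p = 0.13 with an estimated correlation). Of 13 myeloid markers, down as a list, 0 passed and 5 fell adjusted over the list alone (camera, adjusted p = 0.000578, and adjusted p = 0.13 with an estimated correlation). S100a8, a neutrophil gene, was listed at 0 in both GoF libraries and at 166 and 30.3 FPKM in WT, and the globin gene Hbb-bt fell from 913 ± 822 to 11.6 ± 16.4 FPKM (adjusted p = 0.0464), a call that ended in 12 of 17 alternatives (adjusted p up to 0.266). The globin gene Hba-a2 was at 685 and 1255 FPKM in GoF and 640 and 2798 in WT, and the erythroid list did not pass (camera, adjusted p = 0.135).

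Other large changes included Cck, Egfem1, Fam84a and Car12, which were listed at 0 in both WT libraries and averaged 49.1 ± 10.6, 56.6 ± 5.43, 62.3 ± 12.2 and 75.7 ± 29.3 FPKM in GoF. Cox4i2 and Clu had log2 fold changes of 5.40 (SE 0.71) and 4.96 (SE 0.94). Ece1, Sstr2 and Wisp2 had log2 fold changes of -6.13 (SE 0.76), -5.92 (SE 0.49) and -5.04 (SE 0.48). Of 13 stress response genes, Xbp1 rose and 12 did not pass, and 4 rose adjusted over the list alone (camera, adjusted p = 0.00286, and adjusted p = 0.26 with an estimated correlation), a call that ended with sex as a covariate (adjusted p = 0.204, the largest of 17 alternatives). Of 14 hypoxia genes, Ndrg1 rose and 13 did not pass, and 1 rose adjusted over the list alone (camera, adjusted p = 0.0207, and adjusted p = 0.39 with an estimated correlation). That call ended with quantile normalization and without GoF replicate 1 or WT replicate 2, with an adjusted p of up to 0.0752. Of 81 ribosomal protein genes, up as a list, 0 passed, also adjusted over the list alone (camera, adjusted p = 0.00122, and adjusted p = 0.57 with an estimated correlation), and the list turned direction under quantile normalization and with sex as a covariate and lost its call without GoF replicate 2 or WT replicate 1, with an adjusted p of up to 0.737. Both GoF libraries held Y-linked transcripts and no Xist, and both WT libraries held Xist and no Y-linked transcripts. In limma, 0 genes passed with only GoF and WT in the fit (2334 at an unadjusted p under 0.05), 11 with sex as a covariate, 15 with the replicate block and 186 without LoF libraries 2 and 3. The count of 298 was 48 without GoF replicate 1, 79 without GoF replicate 2, 48 without WT replicate 1 and 84 without WT replicate 2, and 0 of the 45 named genes called kept their call under all 17 alternatives, while 14 lost it in over 0.5 of them, among them Pdpn, Wif1, Chad, Gli2, Mmp14 and Csf1.

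Genes that followed the order of the genotypes were counted across all 8 libraries. Dmp1, Gal, Lipi, Frzb, Tnfrsf11b and Sp6 rose from LoF over WT to GoF, and Mmp9, Cxcl12, Lpl, Mmp13, Wisp2 and Mest fell. For Sp6 the step from LoF to WT lay near the floor, from 0 in every LoF library to 0.351 and 0.175 FPKM in WT. Frzb, a secreted Wnt antagonist gene, averaged 1.85 ± 2.20 FPKM in LoF, 9.10 ± 4.07 in WT and 108 ± 10.1 in GoF. Mest averaged 307 ± 119, 102 ± 1.15 and 5.37 ± 4.58 FPKM. In all, 712 genes (5.52%) had their GoF, WT and LoF libraries in this order or its reverse without overlap. Chance gives 0.48% where no groups differ, and any difference between groups, of genotype or sex, can raise the share. Orders with GoF or LoF in the middle were not counted, so the excess does not single out this order. Of the 712, 559 also passed in GoF against LoF, 299 upward and 260 downward. Of the 559, 10 passed in both comparisons with WT. The count of 559 was 326 with the replicate block, 273 without GoF replicate 1 and 296 without GoF replicate 2.

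The last comparison set the mutants against each other through their shared WT libraries. Of the genes called in both, P4ha1 and P4ha2, which encode collagen prolyl hydroxylases, rose in GoF and fell in LoF. Another 8, among them Tnfsf11, Lpl, Col3a1, Igfbp7 and Fgf7, fell in GoF and rose in LoF. These 2 counts compare with 1.21 and 0.66 for independent lists, and the genes not covered by the naming rule were chosen after their values were seen. Htra1, S100a6 and Mt1 were among 12 genes that rose in both mutants, and Kel, Tiam1, Pcca and Stfa1 among 7 that fell in both, against 1.03 and 0.77 for independent lists. Part of that excess may come from the shared controls, which are too few to split. Across all genes, which are not independent replicates, Pearson's r of the fold changes was 0.175 and Spearman's rho 0.197, where unchanged groups simulated against the same WT libraries gave r = 0.577. The covariance was 0.142 and the simulated covariance 0.211, a difference of -0.069. The simulation used a spread per gene shared by all groups, so a smaller spread in WT could give such a difference. It therefore does not show that the mutants oppose each other. Without WT replicate 1, r was 0.324 (simulated 0.729) and the covariance 0.331 (simulated 0.427), and without WT replicate 2, r was 0.357 (simulated 0.731) and the covariance 0.376 (simulated 0.429).

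**Figure D3:**
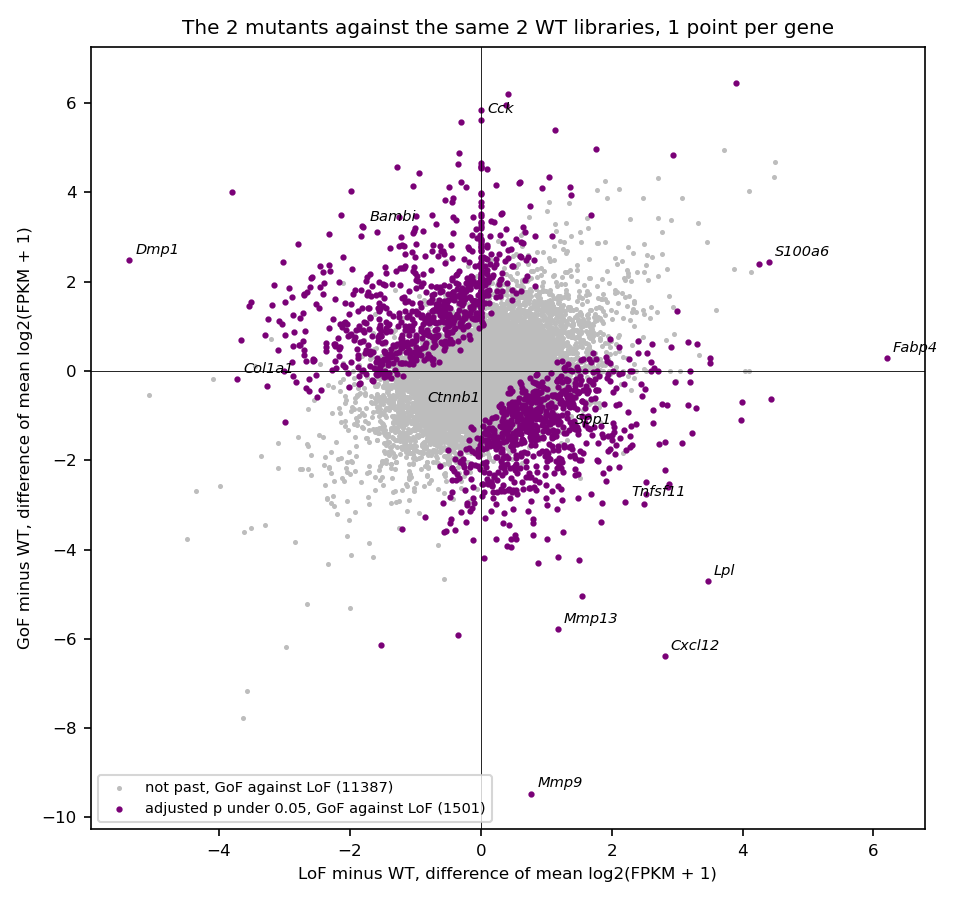
Difference of mean log2(FPKM + 1) from WT in LoF (horizontal axis) and in GoF (vertical axis), 1 point per tested gene. The 1501 purple points passed in GoF against LoF, and r over all points was 0.175.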

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

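The tests of the sex of the mice and of sex chromosome genes were chosen after the results were seen. Among the 4 LoF libraries, 1 library stood apart from the other 3 by more than the critical value of Dixon's test in 24 of 199 measures (165 genes, 27 lists and 7 library measures). In 9 of these the other 3 libraries were listed at or near 0, which makes the ratio 1.0 by construction, so no chance rate is given. All values below are FPKM unless stated. In LoF library 1, Acan was 1.16 (others 14.1 to 17.8), Tnc 106 (others 160 to 174), Tcf7 3.92 (others 2.25 to 2.42), and Gal, Dkk1 and Mpo were 7.33, 0.500 and 0.252 where the others were listed at 0. Its FPKM sum was 293194 (others 343302 to 349378). In LoF library 2, Rpl36a was 952 (others 660 to 692), and Chn1os1, Tiam1, Chac1 and Scin were 1.40, 0.792, 0.364 and 0.208 where the others were listed at 0. The lymphoid list had a mean log2 value of 3.84 there (others 0.92 to 1.37). In LoF library 3, Rps12 was 1330 (others 695 to 718), Pcna 43.8 (others 61.9 to 65.7), Bambi 1.38 (others 3.12 to 3.52), Irx5 2.98 (others 0.455 to 0.504), Notch3 2.85 (others 1.52 to 1.71), and Elane was 0.873 where the others were listed at 0. In LoF library 4, Wls was 186 (others 133 to 138), Top2a 35.9 (others 17.98 to 19.7) and Phospho1 1.00 (others at most 4.27e-05). The mean log2 value was 2.78 for sterol synthesis genes there (others 2.17 to 2.24) and 4.41 for perichondrial markers (others 3.84 to 3.92). No explanation of these single libraries was tested.

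The 298 genes changed between GoF and WT might reflect the sex of the mice, since GoF libraries held Y-linked transcripts and WT libraries Xist. Only 1.7% of the called genes (5 of 298) lie on X or Y, so the called genes were mostly not sex chromosome genes. This share cannot weigh an effect of sex, since genes that differ alike by sex in LoF could hardly be called. Of 5 sex-linked genes, 0 passed. An effect of sex stays open. LoF libraries 2 and 3 (Y-linked) against 1 and 4 (Xist) gave a median log2 difference of -0.03 in the direction of the change (upper quartile 0.20, median change 2.71) over the 199 called genes with a mean LoF FPKM of at least 1. The test was first stated over all 298 (median 0.0, upper quartile 0.18, median change 2.80), and the subset was chosen after that value was seen because many called genes are listed at 0 in LoF. Neither value decides, since the LoF libraries also set the spread used to call genes. Apart from noise, a gene with the same sex difference in LoF reaches a t of at most 3.18, and the smallest called t was 4.48, so the choice of genes fixed a value near 0. The same holds for the fit with sex as a covariate, where all 298 kept their sign (median ratio of log2 changes 1.0), the median SE went from 0.48 to 0.68, and 11 genes passed, 10 of them among the 298. The effect of the genotype stays open too, as sex and genotype coincide in the GoF and WT libraries. The fit with sex tells them apart only through the LoF libraries, and only if sex acts alike there.

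Ctnnb1 averaged 79.3 FPKM in GoF and 142 in WT, a difference that did not pass (adjusted p = 0.176). Loss of exon 3 (chromosome 9, 120950522 to 120950749) could remove at most its 228 of 3623 bases, 6.29% of the main transcript, from 1 allele, which argues against it as the cause. Scaling is argued against too, since the log2 fold change was -0.72 with median ratio scaling and -1.11 with quantile normalization. An effect of the genotype on transcript level stays open and was not tested.

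Ribosomal protein genes were higher in LoF than in WT (median log2 fold change 0.62 over 81 genes). Other protein-coding genes of like length and level had a median of 0.28 (147 genes, quartiles -0.11 to 0.55), so a bias with gene length may account for part of it and stays open, and the match was incomplete (median log2 level 7.94 against 9.08). With the genes resembling ribosomal RNA removed and libraries rescaled, the median was 0.48, narrowly above the bound set beforehand, which argues against them as the whole cause. The β-catenin genotype also stays open.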

How the results depend on the processing

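Sex as a covariate, leaving out LoF libraries 2 and 3, fry, and the simulation with 1 WT library were chosen after the data were seen. Without LoF libraries 2 and 3, LoF against WT compared Xist libraries alone, while GoF against LoF set Y-linked against Xist libraries. Counts moved by over 1.5 times as follows, and the cause was not tested. Fits that left out libraries also had fewer of them, so their moved counts cannot be assigned to a given library. For GoF against WT (298), limma called 0 genes with only these groups in the fit (2334 at an unadjusted p under 0.05), 11 with sex as a covariate, 186 without LoF libraries 2 and 3, and 48 to 337 when each library was left out. For LoF against WT (159) it called 83 with a pseudocount of 0.1, 53 with no filter, 0 with only these groups (1569 at an unadjusted p under 0.05), 54 with no mean-variance trend, 14 with sex as a covariate, 0 without LoF libraries 2 and 3 (1479 at an unadjusted p under 0.05) and 3 to 135 when each library was left out. For GoF against LoF (1501) it called 974 with sex as a covariate, 848 without LoF libraries 2 and 3 and 414 to 1400 when each library was left out. Ordered genes that also passed in GoF against LoF (559) numbered 273 to 727 when each library was left out. With an estimated correlation 0 lists moved in each comparison, and list counts otherwise stayed within 1.5 times. Pearson's r of the mutants (0.175) was 0.303 with sex as a covariate and 0.158 to 0.357 when each library was left out (0.324 and 0.357 without WT replicate 1 or 2, with 1 shared WT library, and 0.158 to 0.168 without any of the mutant libraries). A lone library left in a group was assumed to vary like the others. No named gene that was called reversed in any of the 17 alternatives, while some that were not called turned sign, such as Col1a1 in GoF against WT (log2 fold change -0.39 to 1.21). Of the named genes called, 48 of 100 in GoF against LoF, 0 of 45 in GoF against WT and 0 of 39 in LoF against WT kept their call in all. The last 2 counts were fixed at 0, since no gene passed in either comparison with only its groups in the fit. They are thus no result about the named genes. A gene that left the filter on FPKM in an alternative also counted as not kept. In GoF against WT, Mmp9, Sstr2, Htra1 and Car12 lost their call only with these groups alone in the fit. Depth in reads is unknown, so its limit on low genes was not computed.

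Correlations of deviations from group means between same-numbered libraries were 0.007, 0.03, 0.014, -0.003 and -0.007. No effect on expression shared by replicate number was seen, which does not settle whether the numbers of the labels pair libraries. With the replicate block 15 genes passed in GoF against WT, 1 in LoF against WT and 727 in GoF against LoF. Of these 727, 326 were also ordered.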

Other observations

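Among perichondrial and fibroblast markers, a list that did not pass in any comparison (smallest camera adjusted p = 0.222), the small proteoglycan genes Dcn and Lum ran opposite to Col3a1. Dcn averaged 40.1 ± 14.1 FPKM (SD, n = 4) in LoF, 287 ± 191 (SD, n = 2) in WT and 841 ± 63.0 (SD, n = 2) in GoF, and Lum 35.6 ± 12.2, 194 ± 88.3 and 618 ± 140. Both fell in LoF against WT (limma, adjusted p = 0.0227 and 0.0259). Col3a1, a type III collagen gene, averaged 112 ± 20.4 FPKM in LoF, 19.3 ± 6.44 in WT and 1.80 ± 1.78 in GoF, and it changed in both mutants against WT (adjusted p = 0.0256 for LoF and 0.0117 for GoF).

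Of 6 osteoclast markers tested, Mmp9 and Itgb3 were lower in GoF than in LoF, Acp5 was higher and 3 did not pass. Itgb3, an integrin gene, averaged 0.321 ± 0.197 FPKM in GoF and 3.66 ± 0.305 in LoF (adjusted p = 0.0233), and Acp5 19.97 ± 3.35 and 4.17 ± 2.50 (adjusted p = 0.0319). Their calls ended in 5 and 8 of 17 alternatives (adjusted p up to 0.195 and 0.247). Ctsk, the cathepsin K gene, lay between 53.0 and 77.8 FPKM in all 8 libraries. Ctsk was chosen after its values were seen. The osteoclast marker list did not pass in camera in any comparison (smallest camera adjusted p = 0.252), and in GoF against WT its median was 0.01 and its mean -1.32. The test fry called it down in GoF against WT and in GoF against LoF (adjusted p = 0.00057 in each). The lists of Wnt ligands and modulators, osteoclast-regulating ligands, lymphoid, endothelial and sex-linked genes did not pass in camera either (smallest adjusted p = 0.172, 0.37, 0.244, 0.28 and 0.0555). Of these, fry called the osteoclast-regulating ligands down in GoF against LoF (adjusted p = 0.043). In LoF against WT the median and mean differed in sign for Wnt ligands and modulators (0.05 and -0.05), Hedgehog genes (0.25 and -0.06) and lymphoid markers (-0.37 and 0.22).

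Xist was 26.0 and 13.2 FPKM in LoF libraries 1 and 4, 12.9 and 14.2 in WT, and 0 in LoF libraries 2 and 3 and in GoF. Ddx3y, a Y-linked gene, was 16.2 and 6.87 FPKM in LoF libraries 2 and 3, 19.1 and 12.8 in GoF, and 0 elsewhere. The labels do not give the sex of the mice. Globin transcripts were highest in WT library 2 (Hba-a1 2473 and Hbb-bs 3760 FPKM).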
